A study of Mus musculus with 24 samples.

How the data were processed

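Liver RNA from 24 male C57BL/6 mice was measured on 24 arrays, 3 for each of 8 groups: control (JNK1f/f) after sham surgery or bile duct ligation, and JNK1-/- and JNK1Δhepa after ligation, each at 48 h and 28 d. Per the labels' protocols, RNA was extracted with TRIzol followed by RNeasy columns, had an integrity number over 8.0, and was amplified from 100 ng and labelled with biotin. The values are log2 intensities per probe set that the authors made with RMA before they were deposited, per the submitters' processing notes. The version and settings of RMA, the genome build behind the probe sets and the position of the Mapk8 probes relative to the deleted part of the gene are not given in the sources used here. Raw image files were not used here.

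The deposited file held 35556 probe sets, of which 21218 carried 1 gene symbol, 1881 several and 12457 none. Probe sets with 1 symbol were kept, and the brightest by its mean over all arrays stood for each of 18820 symbols. Gene numbers linked 21185 of these probe sets to a table of mouse genes on assembly GRCm38.p6, and 33 were not found there. That table was used only for names, chromosomes and neighbours. No pair of arrays was identical, and the highest correlation between arrays was 0.9969. The number of arrays sets the precision, with a median SE of 0.129 for a difference between groups and 0.183 for an interaction.

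Differences were estimated with limma 3.58.1 in R 4.3.3, in 1 linear model with a mean for each of the 8 groups over all 24 arrays, 16 residual degrees of freedom and moderated variances (prior degrees of freedom 3.55). Tables were read with data.table (version 1.17.8). P-values were adjusted by the method of Benjamini and Hochberg over the genes of a comparison, and a gene was called at an adjusted p under 0.05. There were 12 comparisons: ligation against sham in control liver at each time and the interaction of ligation and time, sham at 28 d against sham at 48 h, each mutant against control after ligation at each time, JNK1-/- against JNK1Δhepa at each time, and the change of each mutant difference from 48 h to 28 d. P-values rest on variances pooled over groups, which understate the spread in control liver ligated for 28 d (median SD 0.187, elsewhere 0.115 to 0.139). The labels identify animals only by replicate number.

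The comparisons, 30 gene lists for liver cell types and pathways and the alternatives were choices made before the data were examined. Lists were tested with camera in limma at a preset correlation between genes of 0.01, again with a correlation estimated from the data, and with the rotation test fry, with p-values adjusted over the 30 lists. Members were also adjusted over their list alone. Genes raised or lowered by ligation in control liver were tested in the mutants with fry, using the set from the other time point. Chance agreement between the mutants, which share control arrays, was simulated in 100 draws by setting all 3 groups to the control mean and adding residuals drawn from the 24 arrays. Genes near Mapk8 were counted within 20 Mb and compared with all others by Fisher's exact test. Genes shared by the JNK1-/- comparisons were counted against independent lists by the hypergeometric distribution, and their closeness on chromosomes was compared with 10000 random sets.

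Named genes followed a fixed rule. For the ligation comparisons and each mutant against control, it took up to 8 genes per direction with the largest change among called genes whose groups did not overlap. It took up to 4 per direction in the other comparisons, and up to 4 members with the smallest p of each list described. Predicted genes and receptor or antibody gene families were left out, and Mapk8, Mapk9, Mapk10 and Nnt were added to every genotype comparison. Among these, genes whose call held without any single array were preferred in the text.

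The scripts were tested on simulated data with known changes, 18820 genes per comparison. At a log2 change of 1 the share of changed genes called was 80.6% for ligation at 48 h, 86.57% for ligation at 28 d, 88.06% and 86.57% for JNK1-/- at 48 h and 28 d, and 85.07% and 88.06% for JNK1Δhepa. At a log2 change of 0.5 it was 32.84%, 47.76%, 44.78%, 37.31%, 41.79% and 38.81% in the same order, and at 2 it was 98.48% or more. False calls made up 1.299% to 5.389% of the genes called. The simulated noise was independent between genes and had the same SD in every group. These rates thus leave out correlation between genes and the larger spread of control liver ligated for 28 d.

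Arrays with the same replicate number were checked for pairing by correlating their deviations from the group means. All correlations passed 0.1 in a single comparison, JNK1Δhepa against control at 28 d (0.50, 0.24 and 0.16), although not every sample correlated best with its own number. The labels do not say what a replicate number marks.

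Alternatives tried were quantile normalization, centring each array on its median, leaving out the dimmest 30% of genes, a trended and robust variance model, array quality weights, the replicate number as a block, the mean of the probe sets of a symbol, all probe sets, fits to the arrays of a time point or of the compared groups, a further minimum of 1.5-fold, and leaving out each array in turn. Ligation at 48 h was also compared with the sham arrays of 28 d.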

Results

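Gene expression was measured in livers of male mice on 24 arrays, 1 per RNA sample, in 8 groups of 3. Control mice carried Jnk1 alleles flanked by recombination sites (JNK1f/f). JNK1-/- mice lacked the gene in every cell, and JNK1Δhepa mice had lost it through a Cre recombinase driven by the albumin promoter, which is active in hepatocytes. Jnk1 encodes a stress-activated kinase that phosphorylates Jun and carries the gene symbol Mapk8. Livers were taken 48 h or 28 d after bile duct ligation (BDL), an operation that blocks bile flow and leads to cholestatic injury, growth of bile ducts and scarring. Sham-operated animals were included for the control genotype at both times. The values were log2 intensities for 18820 gene symbols. The median standard error (SE) of a difference between groups was 0.129 on the log2 scale.

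Mapk8 itself was examined on each array before any comparison. In the 6 JNK1-/- livers its log2 intensity lay at 6.17 or lower, with means of 5.87 ± 0.46 (SD, n = 3) at 48 h and 5.63 ± 0.46 (SD, n = 3) at 28 d. The 9 control arrays other than those labelled control sham 48 h lay between 7.37 and 7.67. In 5 of the 6 JNK1Δhepa livers Mapk8 lay below that range, whereas the array labelled JNK1Δhepa 28 d replicate 1 read 7.67, at the control level. The 3 arrays labelled control sham 48 h read 6.67 to 6.93, below every other control array. Replicates 1 and 3 lay within the range of the JNK1Δhepa livers, 6.76 to 7.67, and replicate 2 (6.67) below it. Mapk9, which encodes JNK2, differed on those 3 arrays from the other control arrays by a mean of -0.03. The position of the Mapk8 probes is not given, so the intensity left in JNK1-/- liver cannot be read as intact transcript. Directions drawn below from the arrays labelled control sham 48 h, or from the array labelled JNK1Δhepa 28 d replicate 1, carry these readings with them.

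**Figure D1:**
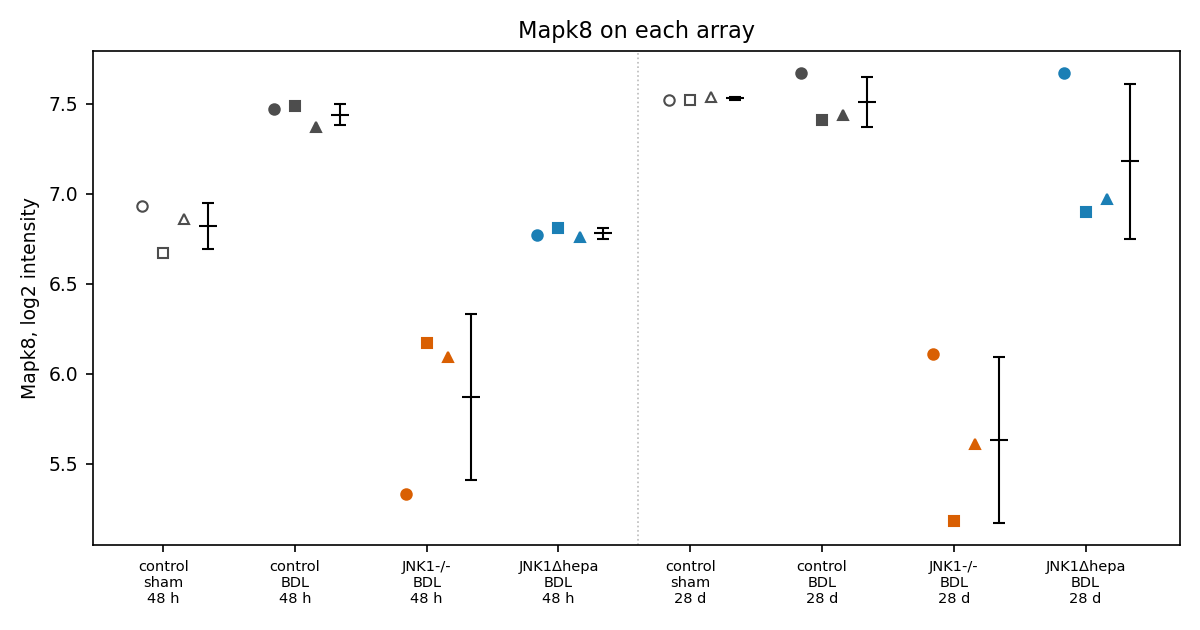
Log2 intensity of Mapk8 on each of the 24 arrays, by genotype, surgery and time; circles, squares and triangles are replicates 1, 2 and 3, open symbols are sham surgery, and bars give the group mean ± SD (n = 3). JNK1-/- livers lie at 6.17 or lower, and the 3 arrays labelled control sham 48 h lie at 6.67 to 6.93, beside the JNK1Δhepa livers.

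The response of control liver to acute cholestasis was addressed by comparing ligation for 48 h with sham surgery. Mybl1, a transcription factor of the MYB family, rose 19.5-fold (log2 difference 4.29, SE 0.63, adjusted p = 0.000264, n = 3 per group). Elovl7, a fatty acid elongase, rose 12.3-fold (log2 difference 3.62, SE 0.42). Ccl2, the chemokine that draws monocytes, rose 11.9-fold and Atf3, a stress-induced transcription factor, 11.5-fold (log2 difference 3.53, SE 0.51). Hsd3b5, a male-specific hydroxysteroid dehydrogenase of mouse liver, fell by 4.56 (log2, SE 0.86), and Elovl3 fell by 3.04 (SE 0.66). Cyp7b1, an oxysterol hydroxylase of bile acid synthesis, fell by 2.87 (SE 0.29, adjusted p = 8.77e-06). In all, 1055 genes rose and 720 fell by limma, 433 of these 1775 by at least 2-fold. The sham side of every one of these directions rests on the arrays labelled control sham 48 h. With the sham arrays of 28 d in their place, a choice made after the Mapk8 values were seen, 1280 genes rose and 965 fell. Without the ligated replicate 2, or without replicate 1 or 3 of the arrays labelled control sham 48 h, the count was 1104, 1106 and 1156.

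Cell-cycle, stress and inflammatory lists rose together at 48 h. Of 30 measured proliferation genes 14 rose and 1 fell, 25 and 1 when adjusted over the list alone, with a median log2 difference of 0.90. Camera gave this list adjusted p = 3.14e-10, and adjusted p = 0.216 with an estimated correlation. Cdt1, which helps to load the replicative helicase, and Mcm4, a subunit of that helicase, rose by 1.09 (SE 0.20) and 1.01 (SE 0.23). Among 22 NRF2 and oxidative stress genes 12 rose and none fell (13 adjusted over the list alone), with a median of 0.59 and adjusted p = 1.24e-09 by camera (adjusted p = 0.119 with an estimated correlation). They included Srxn1, which repairs peroxiredoxins (1.90, SE 0.34), and Hmox1, heme oxygenase (1.61, SE 0.33). The 18 JNK kinase and AP-1 genes had 6 members that rose (7 that rose and 1 that fell adjusted over the list alone), a median of 0.40 and adjusted p = 0.000157 by camera (adjusted p = 0.224 with an estimated correlation). Jun rose 5.40-fold (log2 difference 2.43, SE 0.28) and Map3k1, a kinase upstream of JNK, rose by 1.44 (SE 0.15). Without ligated replicates 1 and 3 the JNK kinase and AP-1 median was 0.62 and 0.17. Without 1 array fewer members were called: 3 and 5 proliferation genes without ligated replicates 1 and 2, 4 without replicate 1 or 2 of the arrays labelled control sham 48 h, and 7 NRF2 genes without ligated replicate 3 or that sham replicate 2.

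Inflammatory and duct markers moved in the same direction. Of 28 cytokine and chemokine genes 9 rose and none fell (11 adjusted over the list alone), with a median of 0.64 and adjusted p = 2.4e-06 by camera (adjusted p = 0.119 with an estimated correlation). Cxcl10 rose 8.53-fold (log2 difference 3.09, SE 0.65). Without ligated replicate 3 the cytokine median was 0.35, with 5 called. Macrophage and Kupffer cell markers (25 measured, median 0.42) included 6 that rose, 8 with 1 that fell adjusted over the list alone, at camera adjusted p = 6.7e-05 (adjusted p = 0.244 with an estimated correlation). Cd14 rose 7.50-fold (SE of the log2 difference 0.59) and Ccr2, the receptor of Ccl2, by 2.02. Cholangiocyte markers had a median of 1.003 over 19 genes, with 6 that rose (8 adjusted over the list alone) and adjusted p = 1.55e-07 by camera (adjusted p = 0.244 with an estimated correlation). Elf3, an epithelial transcription factor, rose 9.67-fold (SE of the log2 difference 0.50). The markers called were 3 without ligated replicate 1 or 3 and 2 without any 1 of the arrays labelled control sham 48 h. Matrix remodelling genes (22 measured, median 0.73) included 6 that rose (9 adjusted over the list alone) at camera adjusted p = 3.9e-06 (adjusted p = 0.238 with an estimated correlation), with Timp1, an inhibitor of matrix metalloproteinases, at 7.49-fold (SE of the log2 difference 0.51).

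Several hepatocyte lists fell over the same 48 h. Of 19 male-biased liver genes 12 fell and none rose (13 adjusted over the list alone), with a median of -0.99 and adjusted p = 1.24e-09 by camera (adjusted p = 0.119 with an estimated correlation). Mup21, a major urinary protein, fell by 1.82. Fatty acid oxidation and PPAR-alpha genes had 11 members that fell of 23 (13 adjusted over the list alone; median -0.37, camera adjusted p = 2.4e-06, adjusted p = 0.119 with an estimated correlation). Ppara, the transcription factor that drives this pathway, fell by 1.14 (SE 0.12, adjusted p = 8.77e-06) and Angptl4, one of its targets, fell by 2.27 (SE 0.31). Of 15 bile acid synthesis genes 5 fell (8 adjusted over the list alone), at a median of -0.36 and adjusted p = 2.08e-05 by camera (adjusted p = 0.119 with an estimated correlation). The 29 hepatocyte secretory and metabolic genes included 7 that fell (9 adjusted over the list alone; median -0.16, camera adjusted p = 0.000108, adjusted p = 0.134 with an estimated correlation), among them G6pc, the last enzyme of glucose release, which fell by 1.87 (SE 0.34). Without ligated replicate 2 the members called in these 4 lists were 6, 7, 2 and 3. Without replicate 1 of the arrays labelled control sham 48 h, 7 male-biased, 2 bile acid and 4 hepatocyte genes were called, without its replicate 2, 2 bile acid and 4 hepatocyte genes, and without its replicate 3, 7 fatty acid oxidation genes. In total 19 of 30 lists passed with the preset correlation, 15 upward and 4 downward, none with an estimated correlation, and 14 by the rotation test fry.

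Chronic cholestasis in control liver was examined by the same comparison at 28 d. Sult1e1, estrogen sulfotransferase, rose 69.0-fold (log2 difference 6.11, SE 0.68, adjusted p = 3.15e-06, n = 3 per group). Bmper, a secreted modulator of bone morphogenetic proteins, rose 23.3-fold, Gpnmb, a glycoprotein of lipid-laden macrophages, 15.8-fold (log2 difference 3.98, SE 0.51), and Lcn2, an iron-binding acute phase protein, 14.1-fold (log2 difference 3.82, SE 0.42). Hsd3b5 fell by 8.50 (log2, SE 0.86, adjusted p = 1.22e-06), Elovl3 fell by 7.29 (SE 0.66), Slco1a1, an organic anion transporter of male hepatocytes, fell by 6.54 (SE 0.46) and Mup21 fell by 5.38 (SE 0.28, adjusted p = 5.82e-10). By limma 2199 genes rose and 2161 fell, 1024 of these 4360 by at least 2-fold, 633 upward and 391 downward. Centring each array on its median moved the median of all genes from -0.03 to -0.12 and the split to 1660 genes that rose and 3693 that fell. A fit to only these 6 arrays called 1765 genes.

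**Figure D2:**
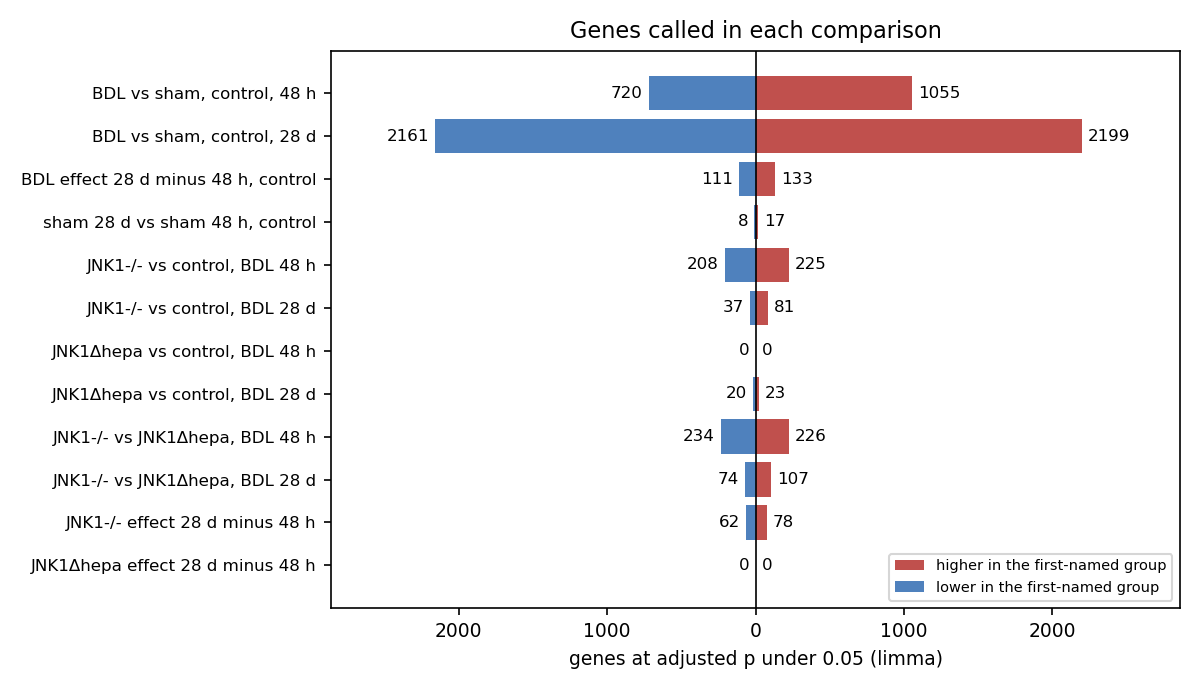
Number of genes at adjusted p under 0.05 by limma in each of the 12 comparisons (n = 3 arrays per group), higher (right) or lower (left) in the group named first. Ligation for 28 d in control liver changed 4360 genes, and the JNK1Δhepa comparison at 48 h none.

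Matrix, macrophage, duct and mesothelial lists rose at 28 d. Of 28 collagen and fibrillar matrix genes 10 rose and none fell (11 and 1 adjusted over the list alone), with a median of 0.69 and adjusted p = 1.49e-05 by camera (adjusted p = 0.394 with an estimated correlation). Nid1, a basement membrane protein, rose 5.99-fold (log2 difference 2.58, SE 0.23) and Col1a1, the main chain of scar collagen, 3.37-fold (log2 difference 1.75, SE 0.39, adjusted p = 0.00287). The matrix remodelling list had 16 of 22 members that rose and 1 that fell (17 and 1 adjusted over the list alone; median 1.17, camera adjusted p = 2.59e-08, adjusted p = 0.205 with an estimated correlation), and its Timp1 rose 8.85-fold. Of 18 TGF-beta response genes 8 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.58, camera adjusted p = 6.4e-05, adjusted p = 0.205 with an estimated correlation), with Ccn2, a matricellular growth factor, at 5.69-fold (SE of the log2 difference 0.31). Stellate cell and myofibroblast markers did not pass (24 measured, 4 that rose both over all genes and adjusted over the list alone, median 0.52, camera adjusted p = 0.0509), although Vim rose by 1.36. Macrophage markers rose in 18 of 25 cases and fell in none (20 adjusted over the list alone), with a median of 1.01 and adjusted p = 1.24e-11 by camera (adjusted p = 0.0841 with an estimated correlation). Cd68 rose 2.85-fold (log2 difference 1.51, SE 0.18), Trem2 by 1.72 and C1qc by 1.17. Cholangiocyte markers had a median of 1.20 with 6 of 19 that rose (8 adjusted over the list alone; camera adjusted p = 0.000119, adjusted p = 0.394 with an estimated correlation), among them Bicc1 at 4.09-fold (SE of the log2 difference 0.30). Mesothelial genes rose in 5 of 11 cases (6 adjusted over the list alone; median 0.76, camera adjusted p = 0.00425, adjusted p = 0.394 with an estimated correlation). In a fit to only these 6 arrays the call of Col1a1 was lost, at adjusted p = 0.0799 (0.000276 to 0.0799 over its alternatives).

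Control livers ligated for 28 d were the most variable group: 360 genes had an SD above 1 among the 3 arrays, against 9 to 161 in the other groups. Replicate 3 carried more duct and matrix signal than the other two, as the plot of list levels by array shows. Without it the fit called 16 lists instead of 19: the cholangiocyte call was lost (median 0.39, adjusted p = 0.0834) and the mesothelial one (0.32, adjusted p = 0.0583), the collagen median was 0.27 and the remodelling median 0.72, and 6 collagen, 3 cholangiocyte and 3 mesothelial genes were called. Without replicate 1 it was 17, 11 and 3, with 8 stellate cell markers. Without replicate 2 the mesothelial median was 1.25 with 8 called, and without sham replicate 1, 3 cholangiocyte genes were called.

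Genes of hepatocyte identity and of lipid and bile acid metabolism fell at 28 d. All 19 male-biased genes fell, with a median of -2.81 and the same 19 adjusted over the list alone. Camera gave adjusted p = 1.2e-20, and the call held with an estimated correlation (adjusted p = 0.00828). Of 14 female-biased genes 5 rose (5 adjusted over the list alone; median 0.63, camera adjusted p = 0.0154, adjusted p = 0.268 with an estimated correlation), among them Fmo2, a flavin monooxygenase, at 7.25-fold (log2 difference 2.86, SE 0.30). Bile acid synthesis genes fell in 11 of 15 cases (11 adjusted over the list alone), with a median of -0.62 and adjusted p = 2.94e-06 by camera (adjusted p = 0.0841 with an estimated correlation); Cyp7b1 fell by 4.09 (SE 0.29). The 20 genes of bile transport were split, with 5 that rose and 4 that fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.839). Abcb1a, a canalicular export pump, rose by 2.90, while Slco2b1, an uptake transporter, fell by 0.95. Fatty acid oxidation had 12 of 23 genes that fell and 1 that rose (12 and 1 adjusted over the list alone; median -0.47, camera adjusted p = 6e-05, adjusted p = 0.205 with an estimated correlation). For fatty acid and triglyceride synthesis 8 of 25 fell and 2 rose (9 and 3 adjusted over the list alone; median -0.36, camera adjusted p = 0.00961, adjusted p = 0.394 with an estimated correlation), with Mlxipl, the carbohydrate response factor, down by a log2 difference of -1.35. Hepatocyte secretory and metabolic genes fell in 16 of 29 cases (17 adjusted over the list alone; median -0.21, camera adjusted p = 0.000222, adjusted p = 0.205 with an estimated correlation), Foxa2, a liver transcription factor, by 0.97 (SE 0.13). Interferon response genes fell in 11 of 27 cases (12 adjusted over the list alone), at a median of -0.54 and adjusted p = 0.000222 by camera (adjusted p = 0.439 with an estimated correlation), with Isg15 at -0.80. Acute phase genes rose in 15 of 28 cases and fell in 2 (18 and 2 adjusted over the list alone; median 0.55, camera adjusted p = 3.44e-07, adjusted p = 0.268 with an estimated correlation). Without ligated replicate 1 the calls of the fatty acid synthesis and interferon lists were lost (medians -0.22 and -0.34, adjusted p = 0.0732 and 0.1), with 6 interferon genes called, and without ligated replicate 2 the former had a median of -0.57. The female-biased median was 0.16 and 0.37 without ligated replicates 1 and 2, and 0.21 without sham replicate 2. Without sham replicate 1, 10 hepatocyte genes were called. Of the 30 lists 19 passed, 13 upward and 6 downward; 1 passed with an estimated correlation and 19 by fry.

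**Figure D3:**
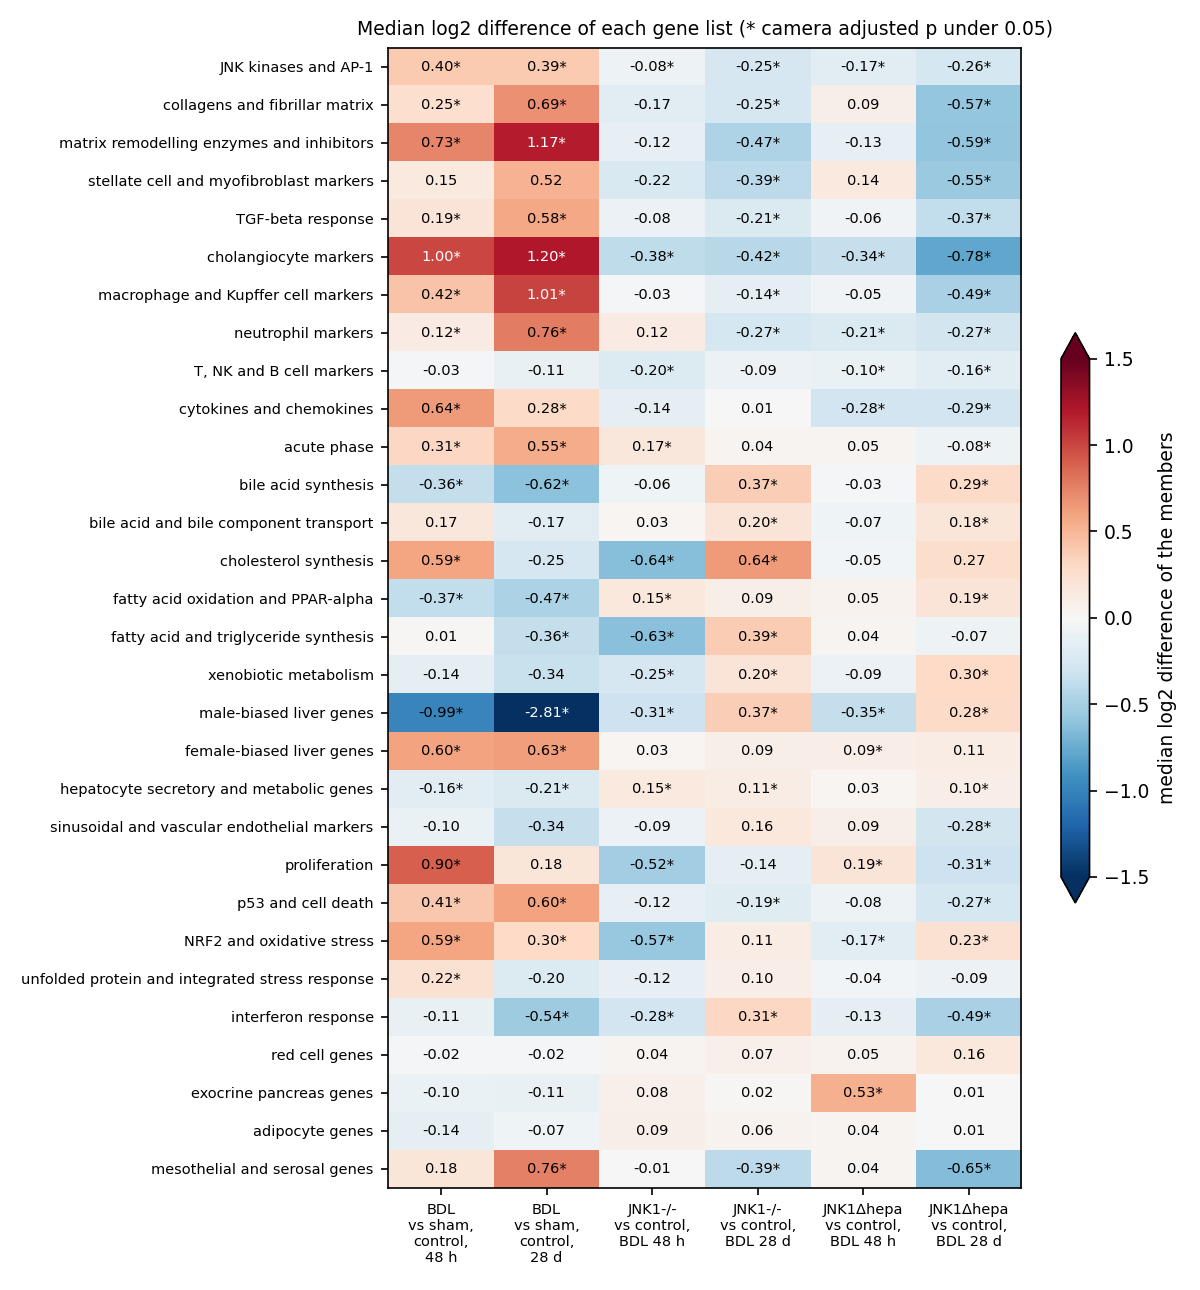
Median log2 difference of the measured members of each of the 30 gene lists (y axis) in the 6 main comparisons (x axis, n = 3 arrays per group); an asterisk marks a camera adjusted p under 0.05 with the preset correlation. The male-biased list has the lowest median, -2.81 after ligation for 28 d in control liver.

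Whether the effect of ligation differed between the times was tested as an interaction. Sult1e1 rose more at 28 d than at 48 h by 5.04 (log2, SE 0.96, adjusted p = 0.0118, n = 3 per group) and Bmper by 4.18 (SE 0.74), while Serpina4-ps1, a serpin pseudogene, went further down by a difference of -5.94 (SE 0.66) and Sult2a8, a bile acid sulfotransferase, by -5.08. Among the 19 male-biased genes 9 had a lower ligation effect at 28 d (13 adjusted over the list alone; median -2.04, camera adjusted p = 2.83e-16), and this list passed with an estimated correlation as well (adjusted p = 0.0246). Slco1a1 had an interaction of -4.86 (SE 0.65). Macrophage markers had 3 higher effects at 28 d (6 adjusted over the list alone; median 0.66, camera adjusted p = 6.08e-07, adjusted p = 0.606 with an estimated correlation), C1qc among them (1.11, SE 0.20, adjusted p = 0.00929). C1qc alone was called without sham 28 d replicate 3, ligated 48 h replicates 2 or 3 or replicate 3 of the arrays labelled control sham 48 h. The others were Mpeg1 (adjusted p = 0.000304 to 0.0751 over its alternatives) and Vsig4 (0.00562 to 0.112), and Vsig4 was also lost without ligated 28 d replicate 1, sham 28 d replicate 1, ligated 48 h replicate 1 and sham 48 h replicates 1 and 2. Proliferation genes had a median of -0.68 with no member called, over all genes by limma or adjusted over the list alone (camera adjusted p = 1.45e-06, adjusted p = 0.672 with an estimated correlation), and of -0.42 without ligated 28 d replicate 1 (2 called without its replicate 3). In total 133 genes had a higher and 111 a lower effect at 28 d, with 2834 at an unadjusted p under 0.05; with arrays centred on their medians the split was 98 and 201. The count rose to 612 without ligated 28 d replicate 3 and to 391 without ligated 28 d replicate 2. It fell to 140, 138 and 115 without sham 28 d replicates 1, 2 and 3, to 118 and 113 without ligated 48 h replicates 1 and 2, and to 112, 115 and 112 without replicates 1, 2 and 3 of the arrays labelled control sham 48 h.

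The sham groups differed in time after surgery and in age, 8 weeks at 48 h and 12 weeks at 28 d. Cish, an inhibitor of cytokine and growth hormone signalling, was 7.83-fold higher at 28 d (log2 difference 2.97, SE 0.26, adjusted p = 9.55e-06, n = 3 per group). Of 28 acute phase genes 3 were lower (7 adjusted over the list alone), with a median of -0.28 and adjusted p = 5.4e-12 by camera (adjusted p = 0.807 with an estimated correlation). They were the metallothioneins Mt1 (-2.17) and Mt2 (-2.42) and Lcn2 (-2.39). Their calls were lost without replicate 2 or 3 of the arrays labelled control sham 48 h, at adjusted p = 0.118 and 0.136 for Mt1 (0.0033 to 0.21 over its alternatives), 0.0721 and 0.0974 for Mt2 (3.02e-05 to 0.116) and 0.137 and 0.187 for Lcn2 (0.00037 to 0.187). Without sham 28 d replicate 3, Mt1 stood at adjusted p = 0.092 and Lcn2 at 0.115, and Lcn2 at 0.0665 without sham 28 d replicate 1. By limma 17 genes were higher and 8 lower at 28 d, and 11 and 8 after quantile normalization. The count was 14, 8 and 4 without replicates 1, 2 and 3 of the arrays labelled control sham 48 h, and 14 and 9 without sham 28 d replicates 1 and 3.

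Loss of Jnk1 from the whole body was examined after ligation, where JNK1-/- livers were compared with control livers. At 48 h Slc6a16, a transporter of the neurotransmitter symporter family, was 104-fold higher in JNK1-/- liver (log2 difference 6.70, SE 0.19, adjusted p = 4.74e-15, n = 3 per group). Obp2a, an odorant-binding protein, was 12.0-fold higher, and Slc8a1, a sodium-calcium exchanger, 9.84-fold (log2 difference 3.30, SE 0.31). Car3, a carbonic anhydrase abundant in male liver, was lower by a log2 difference of -3.76 (SE 0.69, adjusted p = 0.00598) and Ces1g, a carboxylesterase, by -3.54 (SE 0.43). Mapk8 was lower by -1.58 (SE 0.22, adjusted p = 0.00057), whereas Mapk9 differed by -0.08 (adjusted p = 0.7) and Mapk10, which encodes JNK3, by -0.03. By limma 225 genes were higher and 208 lower. The count was 189 and 161 without control replicates 1 and 2, and 234 without JNK1-/- replicate 1. In a fit to only these 6 arrays it was 121, with the call of Ces1g lost at adjusted p = 0.0714 (1.43e-06 to 0.0714 over its alternatives).

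Lipid genes divided by direction at 48 h. Of 23 fatty acid oxidation and PPAR-alpha genes 6 were higher in JNK1-/- liver and none lower (9 and 2 adjusted over the list alone), with a median of 0.15 and adjusted p = 0.0021 by camera (adjusted p = 0.533 with an estimated correlation). Cpt1a, which admits fatty acids to mitochondria, was 1.71-fold higher (log2 difference 0.77, SE 0.14) and Slc25a20, the carnitine carrier, 1.53-fold. Of 25 fatty acid and triglyceride synthesis genes 6 were lower and 1 higher (15 and 2 adjusted over the list alone), with a median of -0.63 and adjusted p = 9.85e-07 by camera (adjusted p = 0.295 with an estimated correlation). The members called were 0 and 1 without control replicates 1 and 2, and 1 and 4 without JNK1-/- replicates 1 and 3. Cholesterol synthesis genes had a median of -0.64 with no member called by limma or adjusted over the list alone (19 measured, camera adjusted p = 3.05e-05, adjusted p = 0.71 with an estimated correlation). This rested on JNK1-/- replicate 1, whose mean deviation over the list was -1.35, against 0.55 and 0.22 in the other two: without it the median was 0.00 (adjusted p = 0.708), and without JNK1-/- replicate 2 it was -1.04.

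Hepatocyte secretory and metabolic genes were higher at 48 h in 3 of 29 cases (7 adjusted over the list alone), at a median of 0.15 and adjusted p = 7.7e-07 by camera (adjusted p = 0.187 with an estimated correlation), with Pck1, the gatekeeper of gluconeogenesis, at 1.60-fold (log2 difference 0.68, SE 0.12). The call of Pck1 was lost in a fit to only these 6 arrays (adjusted p = 0.0768, within 0.000262 to 0.0768 over its alternatives), and it was the only one of the 3 left without any 1 array other than JNK1-/- replicate 2. Proliferation genes had 1 lower member of 30, Mcm7 (4 adjusted over the list alone; median -0.52, camera adjusted p = 8.34e-08, adjusted p = 0.533 with an estimated correlation). NRF2 and oxidative stress genes had 1 of 22, Me1 (8 adjusted over the list alone; median -0.57, camera adjusted p = 2.6e-07, adjusted p = 0.3 with an estimated correlation). Among 27 interferon response genes 3 were lower (3 adjusted over the list alone; median -0.28, camera adjusted p = 5.32e-06, adjusted p = 0.62 with an estimated correlation), Rsad2, Oasl1 and Oasl2. The call of Mcm7 was lost without each array but control replicate 3 (adjusted p = 0.0758 to 0.252), where 4 members were called, and that of Me1 without control replicates 1, 2 and 3 and JNK1-/- replicate 1 (0.106, 0.108, 0.0741 and 0.163). All 3 interferon calls were lost without control replicates 1 and 2 and JNK1-/- replicate 2 (0.0519 to 0.157), and 1 was left without control replicate 3 or JNK1-/- replicate 3 and 2 without JNK1-/- replicate 1. The lowest values over the alternatives were 0.0054 for Mcm7, 0.00881 for Me1, 0.00268 for Rsad2, 5.09e-05 for Oasl1 and 0.000234 for Oasl2. Without JNK1-/- replicate 2, 3 NRF2 genes were called. Without JNK1-/- replicate 1 the proliferation median was -0.33 and the NRF2 median -0.20, and without control replicates 1 and 3 the former was -0.35 and -0.79. Altogether 13 of 30 lists passed, 3 upward and 10 downward, none with an estimated correlation and 4 by fry.

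At 28 d Slc6a16 was again higher in JNK1-/- liver (log2 difference 6.78, SE 0.19, adjusted p = 3.76e-15, n = 3 per group). Tead2, a transcription factor of the Hippo pathway, was 4.24-fold higher (log2 difference 2.08, SE 0.17) and Mid1, an X-linked ubiquitin ligase, higher by 1.86 (SE 0.30). Mapk8 was lower by -1.87 (SE 0.22, adjusted p = 0.000102) and Cd163, a haemoglobin scavenger receptor of macrophages, by -1.44 (SE 0.24). Mapk9 differed by 0.15 (adjusted p = 0.445) and Mapk10 by -0.10. By limma 81 genes were higher and 37 lower. With arrays centred on their medians the split was 154 and 33. The count was 56 and 78 without JNK1-/- replicates 1 and 2, and 413 without control replicate 2. A fit to only these 6 arrays called 1 gene, with 1170 at an unadjusted p under 0.05. In it the calls of Mapk8 and Cd163 were lost, at adjusted p = 0.144 (from 1.19e-05 over its alternatives) and 0.56 (from 0.000195). Those of Tead2 and Mid1 were lost at 0.0912 (from 5.3e-09) and 0.12 (from 0.00188), each the highest value for its gene.

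Collagen and matrix lists were lower at 28 d as groups, with no member called by limma over all genes (2 and 1 remodelling genes without control replicate 1 and JNK1-/- replicate 3). The 28 collagen and matrix genes had a median of -0.25, none adjusted over the list alone, and adjusted p = 0.00943 by camera (adjusted p = 0.65 with an estimated correlation). Postn, periostin, differed by -1.32 (SE 0.46, adjusted p = 0.229). The 22 matrix remodelling genes had a median of -0.47, 2 lower adjusted over the list alone, and adjusted p = 2.73e-05 by camera (adjusted p = 0.42 with an estimated correlation), and Loxl2, a collagen cross-linking enzyme, differed by -1.22 (SE 0.35, adjusted p = 0.131). Without control replicate 3 the collagen median was 0.09 (adjusted p = 0.301), the remodelling median -0.08 (adjusted p = 0.368), the stellate cell median 0.04 (adjusted p = 0.76, from -0.39 and 0.00198 with it) and the cholangiocyte median 0.29 (adjusted p = 0.0117, from -0.42 and 0.0442). The collagen call was also lost without JNK1-/- replicates 1 and 2 (medians -0.14 and -0.17, adjusted p = 0.316 and 0.143), and the list had medians of -0.53 without control replicate 1 and -0.45 without JNK1-/- replicate 3. The remodelling median was -0.23 and -0.75 without JNK1-/- replicates 1 and 3. Without JNK1-/- replicate 1 the stellate cell call was lost (-0.22, adjusted p = 0.115), and the cholangiocyte call without JNK1-/- replicates 1 and 2 (adjusted p = 0.0772 and 0.379). Mesothelial and serosal genes had a median of -0.39 beside these lists, with none of 11 called either way (camera adjusted p = 0.0184, adjusted p = 0.58 with an estimated correlation). Their median was -0.76 with 2 called without control replicate 2, and the call was lost without control replicates 1 and 3 (-0.31 and -0.02, adjusted p = 0.0856 and 0.76) and without JNK1-/- replicate 1 (-0.23, adjusted p = 0.336). Bile acid synthesis genes had a median of 0.37 with 5 of 15 higher adjusted over the list alone (camera adjusted p = 2.73e-05, adjusted p = 0.254 with an estimated correlation), Baat, which conjugates bile acids, at 0.41 (SE 0.11, adjusted p = 0.108). Their median was 0.25 without control replicate 1, and 3 were called over all genes without control replicate 2. Hepatocyte genes had a median of 0.11, none called over all genes (1 without control replicate 2) and 2 adjusted over the list alone (camera adjusted p = 9.57e-06, adjusted p = 0.254 with an estimated correlation). In all 18 lists passed, 8 upward and 10 downward, none with an estimated correlation and 2 by fry; without control replicate 3 the number was 8.

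**Figure D4:**
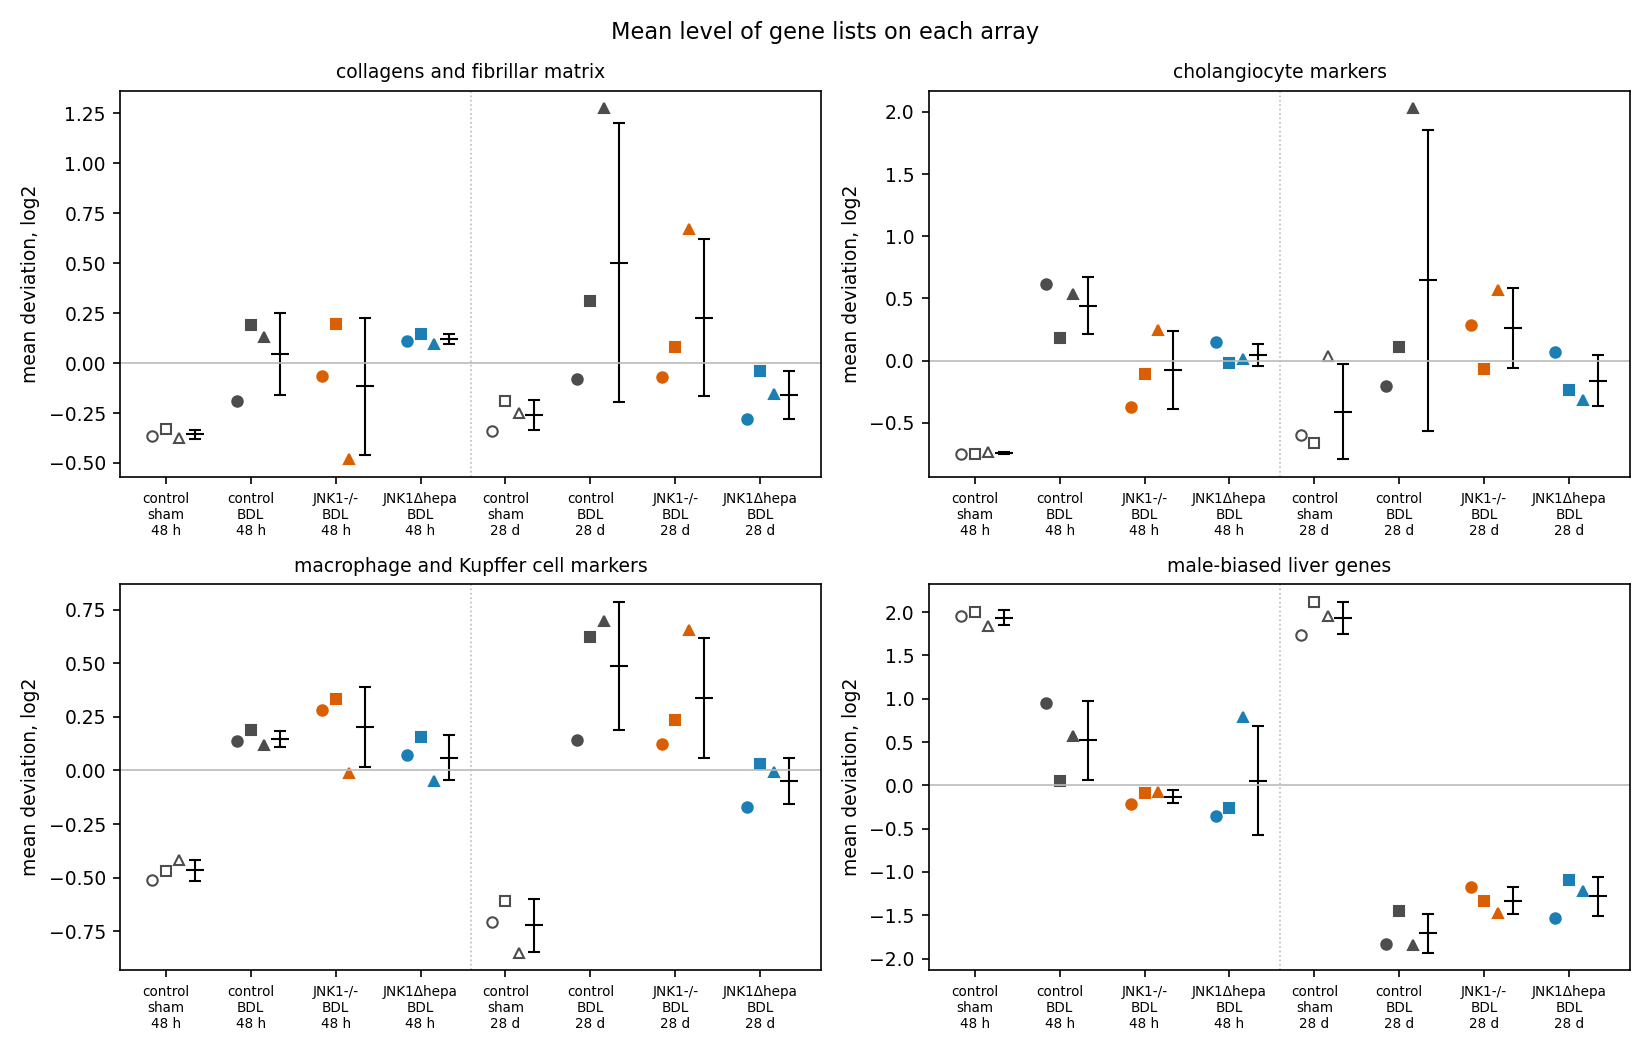
Mean level of 4 gene lists on each of the 24 arrays, as the mean deviation of the members from their average over all arrays (log2, y axis), by group (x axis); circles, squares and triangles are replicates 1, 2 and 3, open symbols are sham surgery, and bars give the group mean ± SD (n = 3). In control liver ligated for 28 d, replicate 3 stands above the other two for the collagen and cholangiocyte lists, and male-biased genes are lower in all ligated groups than in sham groups.

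JNK1-/- livers differed from control livers in the same direction at both times for a common group of genes. Of the genes called, 41 were shared, all with the same sign, 28 higher and 13 lower. Independent lists would share 2.71 (exact hypergeometric p = 2e-37). The lists share pooled variances but no arrays, so this p does not hold. Slc6a16, Tead2, Prelid2, Mid1, Asic5 and Mapk8 belonged to this group, and 9 of the 41 lay on chromosome 14, which carries Mapk8, and 9 on chromosome 7. Leaving out Mapk8, their median difference over both times was 0.93 in the direction of JNK1-/- liver, and 0.11 in JNK1Δhepa liver. In JNK1Δhepa liver 32 of these 40 had less than 50% of the JNK1-/- difference at both times. Bid (-0.40 and -0.47, against -0.72 and -0.87) and Qpctl (0.48 and 0.45, against 0.56 and 0.83) had 50% or more at both times, Igsf23 (-1.93 against -1.74) and Abcc6 at 48 h, and Nkiras1, Lratd2, Amy1 and C1rl at 28 d. Within 20 Mb of Mapk8, 13 of 285 genes were called at 48 h (4.56%, against 2.26% elsewhere, odds ratio 2.06, Fisher's exact test, two-sided p = 0.0163). At 28 d 5 of 285 were called (1.75% against 0.605%, odds ratio 2.93, p = 0.0328 by the same exact test). Within 5 Mb the odds ratios were 0.989 and 0.

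**Figure D5:**
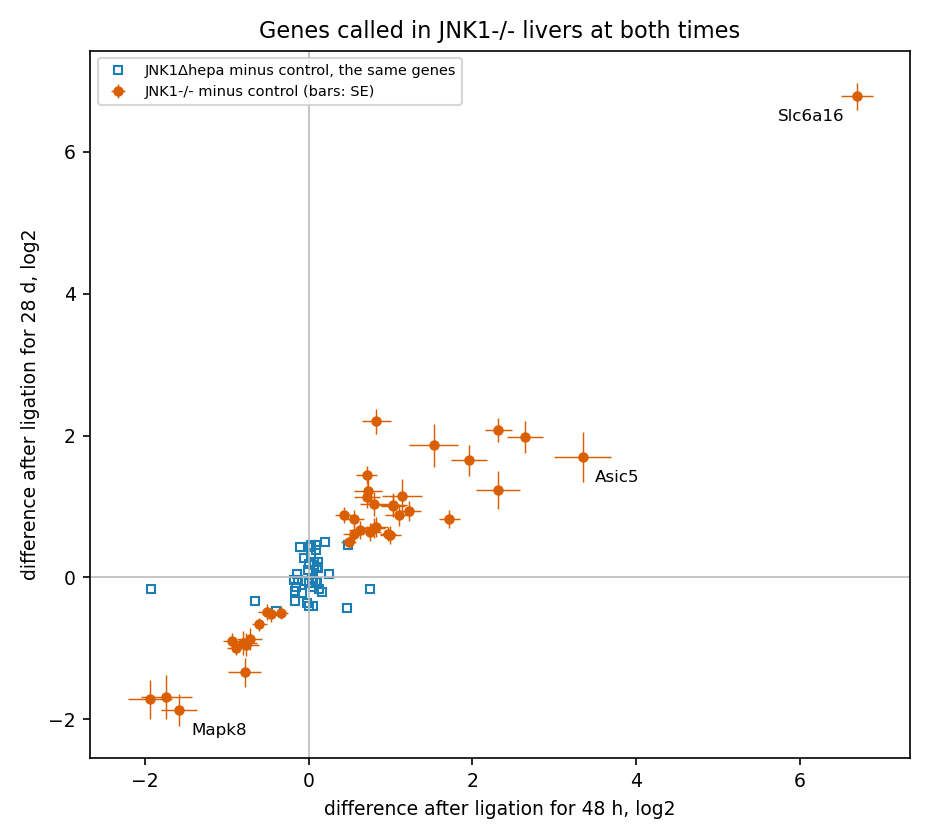
Log2 difference from control after ligation for 48 h (x axis) and 28 d (y axis) of the 41 genes called in JNK1-/- liver at both times (filled circles, bars are SE, n = 3 arrays per group) and of the same genes in JNK1Δhepa liver (open squares). All 41 keep their sign in JNK1-/- liver, and Slc6a16 lies at 6.70 and 6.78. The JNK1Δhepa values, averaged over both times and without Mapk8, have a median of 0.11 in the direction of JNK1-/- liver, with Igsf23 farthest from 0 at -1.93 at 48 h.

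Deletion of Jnk1 in hepatocytes alone was compared with control liver at the same times. At 48 h limma called 0 genes, with 607 at an unadjusted p under 0.05 where chance gives 941, and with array quality weights it called 3. Leaving out control replicate 1 or JNK1Δhepa replicate 3 gave 3 genes and 1 gene. Mapk8 differed by -0.66 (SE 0.22, adjusted p = 1, n = 3 per group), Mapk9 by 0.01 and Mapk10 by -0.01. Nnt, the mitochondrial transhydrogenase that differs between C57BL/6 substrains, differed by -0.98 (SE 0.19, adjusted p = 0.457) by its brighter probe set, while a dimmer one had means of 5.87 in JNK1Δhepa and 6.01 in control liver. Cytokine and chemokine genes had a median of -0.28 with no member called over all genes or adjusted over the list alone (28 measured, camera adjusted p = 3.15e-08, adjusted p = 0.136 with an estimated correlation). Ccl7 differed by -1.09 (SE 0.31) and Tnf by -0.87 (SE 0.30), each at adjusted p = 1. Without control replicate 3 the cytokine median was -0.14. Exocrine pancreas genes had a median of 0.53 with 1 of 22 higher adjusted over the list alone (camera adjusted p = 7.1e-15, adjusted p = 0.239 with an estimated correlation), Try10, a trypsinogen, at 0.65 (SE 0.17). A single liver, JNK1Δhepa replicate 3, carried this list, with a mean deviation of 1.34 against -0.10 and -0.09 in the other two. Without it the median was 0.06 and the call was lost (adjusted p = 0.132). Of the 30 lists 10 passed, 3 upward and 7 downward, and none with an estimated correlation or by fry.

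At 28 d in JNK1Δhepa liver Oasl2, an interferon-induced protein, was 2.54-fold lower (log2 difference -1.35, SE 0.22, adjusted p = 0.0496, n = 3 per group) and Gbp3, an interferon-induced GTPase, 2.08-fold lower. Miox, which degrades inositol, was 3.27-fold higher (log2 difference 1.71, SE 0.35). By limma 23 genes were higher and 20 lower, with 2798 at an unadjusted p under 0.05. Mapk8 differed by -0.33 (SE 0.22, adjusted p = 0.513), with the array labelled JNK1Δhepa 28 d replicate 1 at the control level. With the replicate numbers as a block, which pair the samples in this comparison, 18 genes were called instead of 43, and with arrays centred on their medians the split was 83 and 25. The count was 1985, 129 and 0 without control replicates 1, 2 and 3, and 0, 0 and 6 without JNK1Δhepa replicates 1, 2 and 3. Without control replicate 3 the calls of Oasl2 and Gbp3 stood at adjusted p = 0.198 and that of Miox at 0.226. Without JNK1Δhepa replicates 1, 2 and 3 they were lost as well, Oasl2 at 0.149, 0.136 and 0.0678, Miox at 0.154, 0.164 and 0.0926, and Gbp3 at 0.154, 0.164 and 0.083. Gbp3 was also lost without control replicate 2 (0.0695). Over its alternatives the adjusted p of Oasl2 ran from 0.000343 to 0.633, that of Gbp3 from 0.000611 to 0.633 and that of Miox from 0.00441 to 0.633.

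Lists of matrix, ducts, macrophages and interferon response were lower in JNK1Δhepa liver at 28 d. The 28 collagen and matrix genes had a median of -0.57, none called over all genes and 10 lower adjusted over the list alone, with adjusted p = 5.57e-10 by camera (adjusted p = 0.206 with an estimated correlation). Col6a2 differed by -0.79 (SE 0.20, adjusted p = 0.0808). Matrix remodelling genes had a median of -0.59 and 8 of 22 lower adjusted over the list alone (camera adjusted p = 1.41e-08, adjusted p = 0.206 with an estimated correlation), Timp1 at -1.77 (SE 0.51, adjusted p = 0.123). Of 24 stellate cell markers 1 was lower adjusted over the list alone (median -0.55, camera adjusted p = 4.03e-06, adjusted p = 0.27 with an estimated correlation). Cholangiocyte markers had a median of -0.77 with none of 19 called either way (camera adjusted p = 4.03e-06, adjusted p = 0.27 with an estimated correlation), Krt7 at -1.30. Of 25 macrophage markers 8 were lower adjusted over the list alone (median -0.49, camera adjusted p = 5.57e-10, adjusted p = 0.206 with an estimated correlation). Interferon response genes had 2 of 27 lower, Oasl2 and Gbp3, and 4 adjusted over the list alone (median -0.49, camera adjusted p = 1.35e-08, adjusted p = 0.213 with an estimated correlation). Without control replicate 3 the stellate cell median was -0.14 (adjusted p = 0.0662) and the cholangiocyte median -0.05 (adjusted p = 0.51), so that those calls were lost. The collagen median was then -0.19 (adjusted p = 0.000758), and the macrophage median -0.38 (adjusted p = 2.48e-07). Without control replicate 1 the collagen, stellate cell and cholangiocyte medians were -0.86, -0.99 and -1.22, and 14 collagen, 10 remodelling, 8 stellate cell, 5 cholangiocyte, 10 macrophage and 15 interferon genes were called. Without control replicate 2, 1 stellate cell and 1 interferon gene were called. The interferon median was -0.85 (adjusted p = 8.81e-14), -0.31 (0.000216) and -0.29 (2.57e-05) without control replicates 1, 2 and 3, and -0.30 (0.000385) without JNK1Δhepa replicate 1. Mesothelial and serosal genes had a median of -0.65 as well, with none of 11 called either way (camera adjusted p = 3.7e-05, adjusted p = 0.206 with an estimated correlation), of -0.40 (adjusted p = 0.0046) without control replicate 3 and of -1.11 (3.82e-10) with 4 called without control replicate 2.

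Bile acid synthesis and fatty acid oxidation lists were higher in the same comparison, while fatty acid and triglyceride synthesis did not pass (median -0.07, none of 25 called either way but 2 over all genes without control replicate 1, camera adjusted p = 0.926). Of 15 bile acid synthesis genes 6 were higher adjusted over the list alone and none over all genes (median 0.29, camera adjusted p = 6.23e-06, adjusted p = 0.206 with an estimated correlation), with Akr1d1, a steroid reductase of that pathway, at 0.50 (SE 0.17, adjusted p = 0.185). Among 23 fatty acid oxidation genes 1, Slc25a20 (0.55, SE 0.11), was higher and 5 adjusted over the list alone (median 0.19, camera adjusted p = 0.000225, adjusted p = 0.206 with an estimated correlation). The call of Slc25a20 was lost without control replicate 3 (adjusted p = 0.198) and without JNK1Δhepa replicates 1, 2 and 3 (0.149, 0.164 and 0.104), within 0.00482 to 0.633 over its alternatives. Without control replicate 1, 2 bile acid and 4 fatty acid oxidation genes were called, and 2 of the latter without control replicate 2. In all 23 lists passed, 7 upward and 16 downward, none with an estimated correlation and 3 by fry.

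JNK1-/- and JNK1Δhepa livers were also compared with each other. At 48 h Slc6a16 (6.62, SE 0.19), Obp2a (3.75, SE 0.45) and Slc8a1 (3.35, SE 0.31) were higher in JNK1-/- liver, each by log2 difference with n = 3 per group. Nnt was higher by 1.10 (SE 0.19, adjusted p = 0.00394) by its brighter probe set, while the dimmer one had means of 5.99 in JNK1-/- and 5.87 in JNK1Δhepa liver. Of 25 fatty acid and triglyceride synthesis genes 8 were lower (14 lower and 1 higher adjusted over the list alone; median -0.77, camera adjusted p = 6.04e-08, adjusted p = 0.442 with an estimated correlation), with Acacb, acetyl-CoA carboxylase 2, at -2.12 (SE 0.35, adjusted p = 0.00261). The members called were 4 without JNK1-/- replicate 1, and 3, 4 and 1 without JNK1Δhepa replicates 1, 2 and 3. Proliferation genes were lower in 4 of 30 cases (16 adjusted over the list alone; median -0.71, camera adjusted p = 7.11e-12, adjusted p = 0.442 with an estimated correlation). The 4, Aurka, Cdc20, Plk1 and Ttk, all lost their call without JNK1-/- replicate 1 or JNK1Δhepa replicate 1 (adjusted p = 0.0531 to 0.163). All but Aurka lost it without JNK1-/- replicate 2 or JNK1Δhepa replicate 3 (0.0545 to 0.229), Plk1 and Ttk without JNK1Δhepa replicate 2 (0.0662 and 0.0908), and Ttk without JNK1-/- replicate 3 (0.12). Over the alternatives their adjusted p ran from 0.0016 to 0.0638, 0.000643 to 0.0781, 0.0065 to 0.163 and 0.0208 to 0.229. The proliferation median was -0.46 without JNK1-/- replicate 1, and that of fatty acid synthesis -0.49 without JNK1Δhepa replicate 3. By limma 226 genes were higher and 234 lower. The count was 228 and 287 without JNK1-/- replicates 1 and 2, and 245, 209 and 145 without JNK1Δhepa replicates 1, 2 and 3.

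At 28 d Slc6a16 (6.56, SE 0.19) and Tead2 (2.48, SE 0.17) were higher in JNK1-/- than in JNK1Δhepa liver, and Akr1c18, a hydroxysteroid dehydrogenase, was lower (-2.57, SE 0.32, adjusted p = 0.000442, n = 3 per group). Mapk8 differed by -1.54 (SE 0.22, adjusted p = 0.00114). In a fit to only these 6 arrays Mapk8 stood at adjusted p = 0.0548 (0.000132 to 0.0548 over its alternatives). Interferon response genes were higher in 3 of 27 cases (20 adjusted over the list alone), with a median of 0.71 and adjusted p = 6.53e-15 by camera (adjusted p = 0.817 with an estimated correlation). The 3 were Gbp3, Xaf1 and Psmb8. All lost their call without JNK1-/- replicate 3 or JNK1Δhepa replicate 1 (adjusted p = 0.135 to 0.25), Gbp3 and Xaf1 without JNK1-/- replicate 1 or JNK1Δhepa replicate 2 (0.0701 to 0.104) and Gbp3 without JNK1Δhepa replicate 3 (0.0515). Over the alternatives their adjusted p ran from 0.0147 to 0.233, 0.00982 to 0.25 and 0.00484 to 0.189. Collagen and matrix genes had a median of 0.33 with none of 28 called either way (camera adjusted p = 0.000908, adjusted p = 0.82 with an estimated correlation), a call that was lost without JNK1-/- replicate 3 (median 0.14, adjusted p = 0.218). By limma 107 genes were higher and 74 lower. The count was 82 and 51 without JNK1-/- replicates 1 and 3, and 42 and 82 without JNK1Δhepa replicates 1 (Mapk8 at the control level) and 2.

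Whether a genotype difference changed between 48 h and 28 d was tested as an interaction. In JNK1-/- liver Obp2a (-3.71, SE 0.63, adjusted p = 0.0126) and Slc8a1 (-3.08, SE 0.43, adjusted p = 0.00772) had a lower difference from control at 28 d than at 48 h (n = 3 per group). Of 25 fatty acid and triglyceride synthesis genes 3 had a higher difference at 28 d (17 higher and 2 lower adjusted over the list alone; median 1.17, camera adjusted p = 9.23e-09, adjusted p = 0.384 with an estimated correlation). The members called were 1, 6 and 10 without control 28 d replicates 1, 2 and 3, 0 and 5 without JNK1-/- 28 d replicates 1 and 2, and 0, 0 and 5 without control 48 h replicates 1, 2 and 3. Cholesterol synthesis genes had a median of 1.24, with none of 19 called over all genes (1 without control 28 d replicate 2) and 8 adjusted over the list alone (camera adjusted p = 6.75e-09, adjusted p = 0.53 with an estimated correlation), Insig1, which retains the sterol sensor, at 1.40 (SE 0.37, adjusted p = 0.0789). The cholesterol median was 0.69 without JNK1-/- 48 h replicate 1 and 0.81 without control 28 d replicate 1, whose mean deviations over the list were -1.35 and -1.19. By limma 78 genes had a higher and 62 a lower difference at 28 d, with 2798 at an unadjusted p under 0.05, and 202 and 57 with arrays centred on their medians. Without control 28 d replicates 1, 2 and 3 the count was 52, 442 and 574, and without control 48 h replicates 1 and 2 it was 16 and 25. Without JNK1-/- 28 d replicates 1 and 3 it was 32 and 73, and without JNK1-/- 48 h replicates 1 and 2 it was 48 and 81. In a fit to the arrays compared it was 0, with 1980 at an unadjusted p under 0.05.

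For JNK1Δhepa liver the same interaction called 0 genes by limma, with 1338 at an unadjusted p under 0.05, 221 with array quality weights and 1 with the replicate number as a block. It was 55, 3 and 1 without control 28 d replicates 1, 2 and 3. Collagen and matrix genes had a median of -0.67 (camera adjusted p = 3.94e-11, adjusted p = 0.358 with an estimated correlation) and stellate cell markers -0.82 (camera adjusted p = 1.96e-07, adjusted p = 0.361 with an estimated correlation), with no member called over all genes. Without control 28 d replicate 3 these medians were -0.32 and -0.25, and without control 48 h replicate 1 the stellate cell median was -0.51. Mesothelial genes had a median of -0.65 with none of 11 called either way (camera adjusted p = 3.89e-05, adjusted p = 0.358 with an estimated correlation), and of -1.13 and -0.28 without control 28 d replicates 2 and 3.

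Genes that responded to ligation in control liver were followed into the mutants, each set taken from the time not tested so that set and contrast share no arrays. At 28 d the 1055 genes raised by ligation at 48 h lay lower in JNK1Δhepa than in control liver by a mean of -0.23 (816 of 1055 lower, adjusted p = 0.0336 by fry in limma). The 720 genes lowered by ligation lay higher by 0.136 (546 of 720 higher, adjusted p = 0.0183). In JNK1-/- liver at 28 d the lowered genes lay higher by 0.126 (503 of 720 higher, adjusted p = 0.02), and the raised genes differed by -0.076 (adjusted p = 0.415). Camera with an estimated correlation ended each of these 3 calls at adjusted p = 0.0758. So did sets of genes called with at least a 2-fold change, at 0.138 and 0.326 for raised and lowered genes in JNK1Δhepa and 0.326 for lowered genes in JNK1-/- liver. In JNK1Δhepa liver the raised genes were also lost after quantile normalization (0.0566), and the lowered genes with the set called at 28 d (0.0546). At 48 h no set passed: the means were 0.025 and -0.123 in JNK1-/- liver (adjusted p = 0.548 and 0.201) and -0.061 and -0.007 in JNK1Δhepa liver (adjusted p = 0.201 and 0.993). The 48 h sets rest on the arrays labelled control sham 48 h. The call of the raised genes in JNK1Δhepa liver at 28 d was lost without control replicates 2 or 3 (adjusted p = 0.0883 and 0.228) and without JNK1Δhepa replicates 1, 2 or 3 (0.0728, 0.0688 and 0.0771), within 0.0015 to 0.228 over its alternatives. Without control replicate 3 the calls of the lowered genes were lost too, at adjusted p = 0.147 in JNK1Δhepa and 0.228 in JNK1-/- liver. The raised genes in JNK1-/- liver at 28 d passed without control replicate 1 (mean -0.182, adjusted p = 0.0464).

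The differences of the mutants from control liver were set against each other across genes, which are not independent replicates. Pearson's r was 0.26 at 48 h and 0.35 at 28 d. Both differences use the same 3 control arrays. With this sharing, 3 simulated groups without any difference gave a mean r of 0.47 (SD 0.22) and 0.49 (SD 0.20) over 100 draws. The covariance was 0.0131 at 48 h (simulated mean 0.0174) and 0.0248 at 28 d (simulated mean 0.0188). The same sign was seen in 60.6% and 63.3% of genes, against 66.1% and 66.9% simulated. At 28 d 1 gene was higher and 1 lower in both mutants, where independent lists give 0.099 and 0.0393 and the simulation a mean of 1.55, up to 155. No excess over shared controls was thus shown (simulated covariance SD at 28 d 0.0137).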

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

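The tests of nearby genes, of genes that kept 50%, of probe mismatch, of the arrays labelled control sham 48 h and of the endothelial list were chosen after the result was seen; those of the mutant ratio and of single livers at 28 d were planned. Results that differed between times, by an interaction test in limma, were the 244 genes whose response to ligation changed in control liver and the 140 genes whose JNK1-/- difference changed. The largest in control liver were Sult1e1 (5.04), Bmper (4.18), Igdcc4 (3.09) and Slc8a1 (2.85) upward, and Serpina4-ps1 (-5.94), Sult2a8 (-5.08), Mup3 (-4.96) and Clec2h (-4.93) downward, as log2 differences. For JNK1-/- liver they were Car3 (5.71), Inmt (3.52), Ces1g (3.31) and Clec2h (3.18) upward, and Obp2a (-3.71), Slc10a6 (-3.37), Slc8a1 (-3.08) and Chil3 (-3.07) downward. The calls of all 8 in JNK1-/- liver were lost in a fit to only the arrays compared, at adjusted p = 0.0858 (Slc8a1) to 0.22 (Ces1g), where the lowest values over their alternatives were 0.000648 (Obp2a) to 0.00372 (Clec2h). Without control 48 h replicate 1 those of Car3, Inmt, Ces1g, Clec2h, Slc10a6 and Chil3 were lost (0.0528 to 0.0805), and without control 48 h replicate 2 those of Ces1g, Clec2h and Slc10a6 (0.0521 to 0.053). Without JNK1-/- 28 d replicate 1 Inmt, Ces1g, Clec2h and Slc10a6 were lost (0.0577 to 0.0634), without JNK1-/- 48 h replicate 1 Inmt, Clec2h and Slc10a6 (0.0531 to 0.0592), and without control 28 d replicate 1 Inmt (0.0519).

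The first pattern weighed was the group of 41 genes that differed in JNK1-/- liver at both times. For the group the median ratio of the JNK1Δhepa to the JNK1-/- difference was 0.05 (95% interval 0.02 to 0.16). This argued against loss of Jnk1 from hepatocytes only if deletion was complete. Mapk8, left out, kept under 50% at 48 h and 28 d (-0.66 and -0.33 against -1.58 and -1.87). Bid, Qpctl and 6 others, with 50% or more, stay open. DNA of another strain around Mapk8 and in other stretches goes with the closeness of the 41 genes. Of these, 46.3% had another within 5 Mb, against a median of 19.5% in random sets (permutation p = 0.0031). Odds ratios of calls at 48 h and 28 d were 2.06 and 2.93 within 20 Mb of Mapk8 and 1.65 and 3.19 chromosome-wide. Within 5 Mb, 2 and 0 of 88 genes were too few to decide (0.989 and 0). Probe mismatches with such DNA lower a signal, but 68.3% of the genes were higher. The 13 lower genes stay open, and control DNA was not tested. Loss of Jnk1 from non-hepatocytes stays open, untested, and the JNK1-/- line was bought separately from the floxed line.

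The second pattern, for which no biological explanation was tested, was the low Mapk8 on the arrays labelled control sham 48 h. A lower signal of the whole array or of JNK genes in general was argued against by Mapk9, which differed by -0.03. Livers with the hepatocyte deletion under a control label cannot be told apart from other causes. Mapk8 on the 3 arrays ran from 6.67 to 6.93, around the low end of JNK1Δhepa livers, 6.76. No other value decides. A colony apart from the rest, shared with the JNK1Δhepa 48 h livers, stays open: 7 genes separated these 6 arrays from the other 18, where the 3 other pairs of groups that share only the time had 4 to 6. By its brighter probe set Nnt had its lowest means in these 2 groups (9.14 and 8.95, others 9.59 to 10.34). This was a single gene, seen before it was weighed. Sham 48 h replicate 1 read 9.68, as in other groups, and replicates 2 and 3 read 8.81 and 8.94. The dimmer probe set did not set the groups apart (6.05 and 5.87, others 5.87 to 6.01).

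The third pattern was the lower matrix, stellate cell and duct lists in JNK1Δhepa liver at 28 d, with mesothelial genes at a median of -0.65. A single control liver, replicate 3, with more duct and matrix signal was consistent with the values, since 31.3% of the mean of the 4 list medians (-0.62) was kept without it, and 155% without control replicate 1. Without the array labelled JNK1Δhepa 28 d replicate 1, 103% was kept, which cannot decide, since a liver that kept Jnk1 would weaken a difference made by the deletion rather than produce it. A lower share of all non-hepatocyte cells cannot be told apart from a change in these cells, with an endothelial median of -0.28 (interval -0.40 to -0.13). The hepatocyte deletion itself stays open, untested.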

How the results depend on the processing

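Only the exchange of sham arrays was chosen after the result was seen. Of 399 gene results, 5969 values under the alternatives kept direction and side of the threshold, 607 fell short of it, 110 passed it anew and 23 changed sign, and 129 results fell short somewhere; the cause was not tested unless fewer arrays or genes show it. Of 63 list results with a called member, the count of members moved by over 1.5 times in 42 without some array and in 49 under another setting, and the count adjusted over the list alone in 31 and 35. Signal over background limits genes near the floor, such as Mapk10 at a mean of 3.05 to 3.33. Below, comparisons are ligation at 48 h (A) and 28 d (B), their interaction (C), sham groups (D), JNK1-/- at 48 h (E) and 28 d (F), JNK1Δhepa at 48 h (G) and 28 d (H), JNK1-/- against JNK1Δhepa at 48 h (I) and 28 d (J), and the time interactions of JNK1-/- (K) and JNK1Δhepa (L). Array weights called 3522 genes in A, 1051 in C, 131 in D, 1891 in E, 300 in F, 3 in G, 2357 in H, 1746 in I, 1047 in J, 614 in K and 221 in L, and 6 lists in C and 9 in I. A minimum of 1.5-fold left 1051 in A, 2378 in B, 285 in E, 23 in H and 299 in I. Only the groups compared gave 1765 in B, 126 in C, 63 in D, 121 in E, 1 in F, 3 in H, 153 in I, 84 in J and 0 in K, and only the arrays of the time point 126 in C, 63 in D, 679 in E, 48 in F, 0 in H, 37 in J and 0 in K. Centred arrays gave 187 in F, 108 in H and 259 in K. Quantile normalization, the mean of the probe sets of a symbol and all probe sets each gave 0 in H, and all probe sets 83 in K. Without the dimmest 30%, 5 lists passed in D and 6 in J. The exchange of sham arrays called 2245 genes in A.

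The replicate block called 11 genes in D, 18 in H, 337 in J and 1 in L, and 9 lists in D; it moved no other count of genes or lists by over 1.5 times. Within numbers the correlations were 0.06, 0.05 and -0.05 in A, 0.04, 0.04 and 0.14 in B, 0.00, 0.09 and -0.05 in E, 0.18, 0.08 and 0.50 in F, -0.15, 0.05 and -0.30 in G, -0.09, 0.12 and -0.07 in I, and 0.02, -0.06 and 0.13 in J, with not every sample closest to its own number.

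With an estimated correlation 1 list passed in B and 1 in C, and 0 in each other comparison. By fry 1 passed in C, 4 in E, 2 in F, 3 in H, 2 in I, 1 in K and 0 in D, G, J and L. For ligation sets called at the same time, which share arrays with the test, the means were -0.237 and 0.135 in E and 0.045 for lowered genes in G, all with the sign changed, -0.216 for raised genes in F and 0.092 for lowered genes in H. Camera with an estimated correlation ended 3 calls, at 0.126 (F, lowered), -0.230 and 0.136 (H), each at adjusted p = 0.0758, as did sets of 2-fold genes (0.155, -0.411 and 0.167) and quantile normalization for raised genes in H (-0.215). Within 5 Mb of Mapk8 the odds ratios were 0.989 and 0.

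Leaving out 1 array gave 1104 to 1445 genes in A, 3354 to 4339 in B, 112 to 612 in C, 4 to 21 in D, 161 to 413 in E, 56 to 413 in F, 0 to 3 in G, 0 to 1985 in H, 145 to 382 in I, 42 to 169 in J, 16 to 574 in K and 0 to 55 in L. Lists ranged over 16 to 20, 16 to 22, 12 to 15, 2 to 5, 12 to 18, 8 to 20, 8 to 13, 18 to 24, 9 to 15, 3 to 14, 8 to 17 and 15 to 20 in the same order. Raised and lowered ligation sets ranged from -0.007 to 0.066 and -0.150 to -0.086 in E, -0.182 to 0.021 and 0.062 to 0.156 in F, -0.094 to -0.024 and -0.056 to 0.032 in G, and -0.356 to -0.147 and 0.092 to 0.162 in H. The correlation of the mutants ran from 0.17 to 0.38 at 48 h and 0.23 to 0.60 at 28 d.

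Among genes only uncalled ones changed sign, but called lists did in F without control replicate 3. With the mean of the probe sets Mapk10 was -0.10 in C, 0.04 in H, 0.01 in I, -0.05 in J, 0.02 in K and 0.07 in L, and after quantile normalization 0.00 in G. Mapk9 in G was -0.00 both centred and with array weights. Without 1 array, Klf1 in B ranged from -0.02 to 0.88, Nnt in E from -0.03 to 0.28, Mapk9 in G from -0.04 to 0.05, and Mapk10 from -0.07 to 0.02 in E, -0.05 to 0.04 in G, -0.07 to 0.03 in I and -0.02 to 0.10 in J.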

Other observations

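All splits of arrays given here were planned, and the count of splits that kept the real groups at 1 time was chosen after the result was seen. Several lists in control liver ligated for 28 d held genes that moved apart. Among 12 adipocyte genes Lpl, which frees fatty acids from lipoproteins, rose by a log2 difference of 1.999 (SE 0.22) and Pparg, the adipocyte master regulator, 2.14-fold (SE of the log2 difference 0.13), while Lipe fell by 0.75. The list had 2 that rose and 1 that fell, over all genes and adjusted over the list alone, and did not pass (median -0.07, camera adjusted p = 0.633). Of 21 endothelial markers 6 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.34, camera adjusted p = 0.0585), with Kdr, the VEGF receptor, at -1.23 (SE 0.23) and Dnase1l3, a sinusoidal nuclease, at -1.72 (SE 0.34). The endothelial markers called were 3 without ligated replicate 1 and 4 without sham replicate 1 or 3.

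Xenobiotic metabolism had 13 of 34 genes that fell and 3 that rose (14 and 5 adjusted over the list alone; median -0.34, camera adjusted p = 0.052). Ugt2b1, a glucuronosyltransferase, fell by 2.82 (SE 0.45) and Cyp2c29 fell by 1.21 (SE 0.17), whereas Cyp2c39 rose by 1.53 (SE 0.25). Of 21 T, NK and B cell markers 2 rose and 4 fell (2 and 4 adjusted over the list alone; median -0.11, camera adjusted p = 0.433). Jchain, a plasma cell gene, rose 3.37-fold (SE of the log2 difference 0.33), while Ms4a1, which encodes CD20, fell by 0.75 (SE 0.15) and Cd4 fell by 0.92 (SE 0.20). Of 12 red cell genes 1 fell and none rose (1 adjusted over the list alone; median -0.02, camera adjusted p = 0.439): Alas2, of erythroid heme synthesis, fell by 2.35 (SE 0.30), and 2 were called without ligated replicate 3.

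The 6 arrays of each comparison can be split 3 against 3 in 10 ways, so that a share under 0.05 is not possible. The number of splits with as many called genes as the real one, the real one included, was 1 for ligation at 48 h (highest other count 0), 1 for ligation at 28 d (2), 1 for the sham groups (0), 1 for JNK1-/- at 48 h (9), 2 for JNK1-/- at 28 d (471), 10 for JNK1Δhepa at 48 h (8) and 3 for JNK1Δhepa at 28 d (568). It was 1 and 1 for JNK1-/- against JNK1Δhepa at 48 h and 28 d (5 and 0). Splits with 471 and 568 genes, several times the real 118 and 43, point to structure among the samples. Control livers ligated for 28 d, which both comparisons share, had 360 genes with an SD above 1, against 45 in JNK1-/- and 25 in JNK1Δhepa liver at 28 d. For lists the numbers in the same order were 2 (highest other count 21), 3 (19), 4 (4), 5 (18), 2 (18), 7 (16), 1 (16), 6 (18) and 4 (13).

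For the interactions 100 splits were made. As many genes were called in 13 for ligation (highest other count 2714), 5 for JNK1-/- (1433) and 100 for JNK1Δhepa (213), and as many lists in 39 (21), 87 (20) and 20 (25). These numbers decide nothing about chance, since 21 of the splits kept the real groups, or their mirror image, at 1 or both times and so carried a difference from there into the interaction. They made up 12 of the 13 for ligation and 2 of the 5 for JNK1-/-. A count of 0, as for JNK1Δhepa here and at 48 h, is reached by every split. For the ligation sets the numbers of 10 splits were 8 and 1 for raised and lowered genes in JNK1-/- liver at 48 h (highest other mean 0.087 and 0.107), 6 and 1 at 28 d (0.203 and 0.079), 3 and 9 in JNK1Δhepa liver at 48 h (0.089 and 0.095) and 1 and 1 at 28 d (0.208 and 0.104), sizes without sign.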
